A study of Mus musculus with 6 samples.

How the data were processed

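The study measured RNA from mouse (C57BL/6, wild-type) forelimb cells at embryonic day 13.5. Per the labels, cells carrying both a Sox9-CreERT2 lineage label (tdTomato) and a Scleraxis reporter (ScxGFP) were dissociated with trypsin and sorted by fluorescence from the proximal or the distal part of the dissected forelimb. Sox9 is the transcription factor of cartilage precursors and Scleraxis (Scx) that of tendon precursors, so the gate takes cells that have carried both. Libraries were bulk MARS-seq, a method that sequences only the 3' ends of transcripts. There were 6 libraries, 3 proximal and 3 distal, numbered 1 to 3 in each region. The titles carry the same 3 numbers (389, 390 and 393) in both regions, and the codes DT in proximal and Ole in distal ones. These codes are not interpreted here. Nothing states whether libraries came from separate embryos, litters or pools, so p-values measure only the spread between these libraries, which may be partly technical.

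The deposited table holds raw counts per gene and normalized counts for each library. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.8.3, TopHat2, HTSeq, DESeq2 and the genome build mm10, with no roles. The gene annotation, the strand setting and the use of molecular identifiers are not given in the sources used here. The table lists genes whose deposited counts sum to at least 6 over the 6 libraries, so a gene missing from it was not analysed here. The deposited normalized counts are a signal on an arbitrary scale, made by the authors by dividing each library by 1 size factor; these factors matched median-ratio factors recomputed from the raw counts within a relative tolerance of 1e-06, and the normalized columns were used for nothing else. All tests used the deposited counts. No column belonged to a sample of another series. No row lacked a gene name. The row Rn45s, the 45S pre-ribosomal RNA, was kept in the main test and left out in an alternative; it held 2.20% to 11.7% of counts.

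Regions were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr at its defaults by region (minimum count 10, minimum total 15), which kept 9512 of 13158 genes, and the robust quasi-likelihood F test (glmQLFit, glmQLFTest) with region as the only term. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Fold changes are distal over proximal on the log2 scale, so positive values are higher in distal libraries. Standard errors (SE) were derived from the quasi-F statistic as the size of the log2 fold change over the square root of F. Levels are CPM (counts scaled to a common library total) scaled by TMM, given as mean ± SD over 3 libraries. Total counts per library were 1585631 to 2623788, so 3 counts, the limit that a count of 0 allows, correspond to 1.14 to 1.89 CPM; intervals on counts are exact 95% intervals and cover counting error only. On data simulated from these libraries with 9408 genes passing the filter, the procedure recovered 45% of genes changed by a log2 value of 1 and 96.0% of those changed by 2. Of the called genes, 5.73% were unchanged ones. It was a single random draw with genes drawn independently. Differences between libraries that many genes share were left out, so these shares may not hold for the real data.

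Before the data were examined, 30 gene lists were fixed from textbook knowledge of limb and skeletal development and of other cell types the dissection or the gate could hold, together with the tests and the alternatives. The 26 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry, a test of whether the genes of a list move on balance one way, were alternatives. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The rule for named genes, also set beforehand, took the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and non-overlapping regions (predicted genes left out), up to 4 members of each list with the smallest p, Sox9 and Scx, and any member of 3 limb patterning lists. Some genes that the rule takes are not reported here. A further 31 genes were named after their values were seen: Hoxa3, Hoxa7, Hoxb2, Hoxb3, Hoxb6, Hoxd8, Col2a1, Matn4, Sox6, Tnmd and Msc in the report, and those of the paragraph on contractile, growth factor, matrix and transcription factor genes in the other observations.

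Alternatives set beforehand were DESeq2's size factors, library size alone and upper-quartile scaling, no filter and a filter of 10 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and a minimum log2 change of 1. Alternatives chosen after seeing the data were Rn45s left out, a term for the library set by Rn45s share, and the 2 libraries at the extremes of the second principal component left out. Pairs of libraries within a region differed beyond sampling noise (chi-square over degrees of freedom of 4.69 to 26.3 in 6 pairs), so no pair was merged as a duplicate deposit; repeats of one sample with amplified reads would differ too, so this does not tell technical from biological repeats. Gene positions and transcript sequences came from GENCODE M21 on GRCm38, the assembly that mm10 names; 12658 of 13158 symbols (96.2%) matched 1 gene. Single-value tests used Python 3.11.15 and scipy 1.17.1.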

Results

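RNA from Sox9-lineage, Scx-expressing progenitors of the embryonic day 13.5 mouse forelimb was profiled in 3 proximal and 3 distal libraries. The comparison asks which transcripts differ between cells of one progenitor class taken from different places along the limb. Total counts were 1709551, 1740987 and 2623788 in proximal libraries 1 to 3 and 2143795, 1585631 and 1712586 in distal libraries 1 to 3, and 12600 to 12924 genes had at least 1 count.

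Distal libraries were marked by high transcripts of the 5' HoxA and HoxD genes, the limb regulators Hand2, Tbx5 and Sall1, and cartilage and joint genes such as Sox9, Sox5 and Gdf5. Proximal libraries were marked by the 3' HoxA genes, skeletal muscle transcripts and the tested HoxB and HoxC genes (Hoxb2 to Hoxb6, Hoxc4 to Hoxc6). The proximal limb factors Meis1 and Meis2 and the girdle factor Pax1 were also higher there. Of 9512 genes tested, 322 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 106 higher in distal and 216 higher in proximal libraries. Of these, 92 and 183 respectively changed by at least 1 on the log2 scale. The count fell to 174 without proximal library 2 (42 higher in distal, 132 in proximal), 190 without proximal library 3 (61 and 129), 171 without distal library 1 (57 and 114) and 210 without distal library 2 (84 and 126). With proximal library 1 and distal library 3 left out together, a setting chosen after seeing the data, 441 genes were higher in distal and 421 in proximal libraries.

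Hox genes were among the largest differences. They encode transcription factors that set position along body and limb axes. All 8 tested posterior HoxA and HoxD genes had positive fold changes and 7 passed the test (8 when adjusted over the list alone; camera adjusted p = 8.59e-20). Hoxa11, which patterns the zeugopod and lies on chromosome 6 from 52242106 to 52245810, averaged 131 ± 38.1 CPM (SD, n = 3) in distal and 2.62 ± 1.47 CPM in proximal libraries, a log2 fold change of 5.77 (SE 0.39; edgeR adjusted p = 2.73e-05). Hoxd11 (chromosome 2, 74679557 to 74687016) averaged 219 ± 35.2 CPM and 6.62 ± 2.69 CPM, a log2 fold change of 5.01 (SE 0.26; edgeR adjusted p = 5.32e-06). Hoxa10, Hoxd9, Hoxd10 and Hoxd12 were higher in distal libraries by 3.20, 3.28, 5.07 and 5.36 on the log2 scale, and Hoxa9 by 1.42. The Hoxd12 value rests on only 4 counts over the proximal libraries. The Hoxa9 call was lost without proximal library 2 or 3 or distal library 1 (adjusted p = 0.081, 0.077 and 0.051). Hoxa13, also in the posterior list, was not among the deposited genes and was not analysed. Hoxd13, a marker of the hand plate, did not pass the test at 4.42 (SE 1.07; edgeR adjusted p = 0.068): it stood at 6.93, 6.95 and 54.0 CPM in distal libraries 1 to 3 and at 0.719 to 1.34 CPM in proximal libraries. Hoxd13 passed with DESeq2 (adjusted p = 0.0090) and without any 1 distal library (0.036, 0.030 and 0.045), with adjusted p of 9.87e-06 to 0.24 over all alternatives. The antisense gene Hoxa11os had the largest increase in the set of named genes, 7.02 (SE 0.42), but its span overlaps Hoxa11 and the strand setting of the counting is not given, so reads within the overlap cannot be told apart. The annotated 3' ends, at 52249799 for Hoxa11os and 52242106 for Hoxa11, lie outside it.

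Genes at the other end of the clusters went the other way. All 8 tested HoxB and HoxC genes were higher in proximal libraries (8 also when adjusted over the list alone; camera adjusted p = 4.79e-22), among them Hoxc5 (154 ± 11.5 against 5.12 ± 1.20 CPM, a log2 fold change of -4.88). Hoxb5, Hoxc4, Hoxb4 and Hoxc6 had log2 fold changes of -4.76, -4.32, -4.22 and -4.13, and Hoxb6, Hoxb3 and Hoxb2 of -4.63, -3.72 and -2.81. Of 19 listed HoxB and HoxC genes, 12 were deposited and 8 tested. No gene 5' of Hoxb6 or Hoxc6 in these clusters was tested, so their 5' ends are not covered. Of 7 tested anterior HoxA and HoxD genes, 6 were higher in proximal libraries (6 when adjusted over the list alone; camera adjusted p = 6.86e-13): Hoxa2, Hoxa3, Hoxa5, Hoxa7 and Hoxd4 had log2 fold changes of -4.47, -2.97, -3.73, -1.19 and -3.96. Hoxa4 had 2 counts in all distal libraries against 169 in proximal ones, a distal to proximal ratio of 0.0133 (exact 95% interval 0.0016 to 0.0489). The Hoxa7 call was lost in 5 of the 6 fits with a library left out, all but the one without distal library 3 (adjusted p = 0.083 to 0.21), and with DESeq2 (0.058). Hoxd8 did not pass the test at 1.18 (SE 0.64). These 3 Hox lists also passed with an estimated correlation, at an adjusted p of 0.026 for the posterior list and 0.042 for each of the others. The annotated span of Hoxa3 contains Hoxa4 and Hoxa5, that of Hoxc5 contains Hoxc6 and that of Hoxd4 lies within Hoxd3. Reads in the shared stretches cannot be assigned with certainty. The same holds for Hoxb5 and Hoxb6, which lie within the antisense gene Hoxb5os, as the strand setting is not given.

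**Figure D1:**
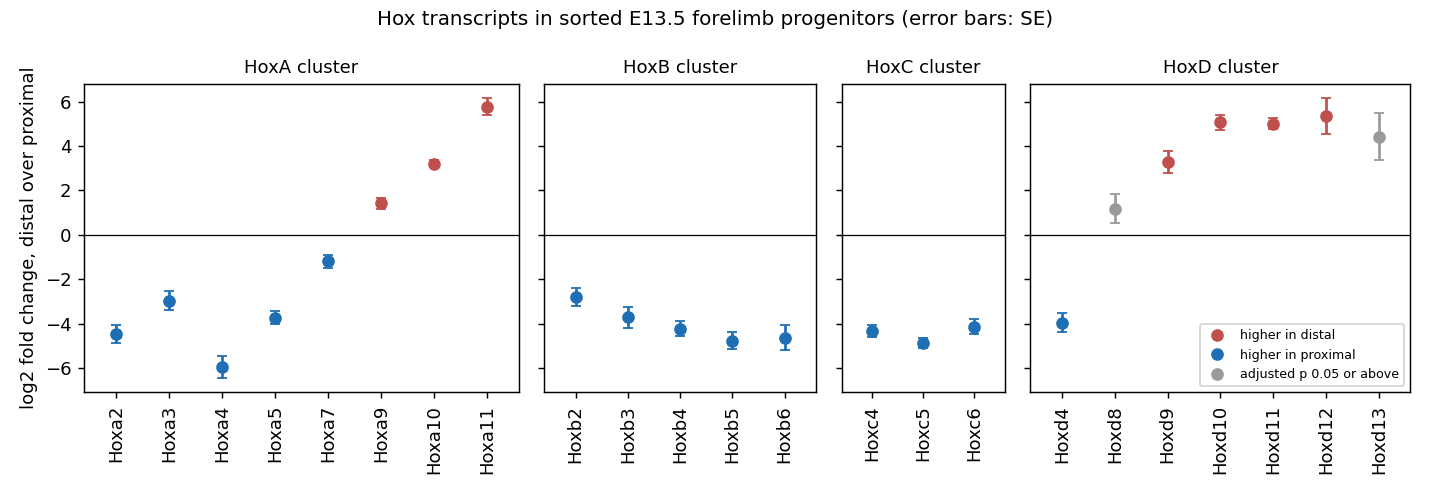
Log2 fold change (y axis, distal over proximal) of each tested gene of the 4 Hox clusters in order of paralog number (x axis); bars are SE from 3 libraries per region, and grey marks an adjusted p of 0.05 or above. HoxA values are -4.47 at Hoxa2, lowest at Hoxa4 (a fitted value that depends on the prior count) and 5.77 at Hoxa11, all HoxB and HoxC genes lie below 0, and Hoxd9 to Hoxd12 lie above 0.

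Known regulators of limb position followed their regions in part. Of 15 proximal limb regulators tested, 5 were higher in proximal and 1 in distal libraries (7 and 3 adjusted over the list alone). Meis1 (chromosome 11, 18879817 to 19018985), a homeobox factor of the proximal limb, averaged 56.6 ± 4.81 CPM in proximal and 6.53 ± 0.53 CPM in distal libraries, a log2 fold change of -3.11 (SE 0.23; edgeR adjusted p = 6.4e-05). Meis2, Irx3, Irx5 and Pax1 (a factor of the shoulder girdle) had log2 fold changes of -2.84, -3.74, -2.14 and -4.13, and Shox2, which is needed for the humerus, was higher in distal libraries by 1.24 (SE 0.27). The Shox2 call was lost without proximal library 1, 2 or 3 or distal library 2 (adjusted p = 0.052, 0.15, 0.14 and 0.073). The members that did not pass included the Meis partners Pbx2 (0.43) and Pbx3 (0.15). The list passed with camera (adjusted p = 0.00088) but not with an estimated correlation (adjusted p = 0.20).

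Of 8 distal limb regulators, 3 were higher in distal libraries and none in proximal ones (4 and 0 adjusted over the list alone): Sall1 by 3.99, Hoxd12 by 5.36 and Cyp26b1, a retinoic acid-degrading enzyme, by 2.16 on the log2 scale. The proximal libraries together held only 6 Sall1 and 4 Hoxd12 counts, so the sizes of these changes are uncertain. In distal libraries 1 to 3, Sall1 stood at 8.91, 12.0 and 29.0 CPM and Hoxd12 at 9.90, 28.4 and 51.3 CPM. The Cyp26b1 call was lost without proximal library 2 or 3 (adjusted p = 0.056 and 0.050). Msx1, Lhx9, Bmp2 and Dlx5 did not pass, with 1.58, 0.30, 0.64 and 0.20. The list passed with camera (adjusted p = 4.23e-07) but not with an estimated correlation (adjusted p = 0.093); 2 of its tested members, Hoxd12 and Hoxd13, are also in the posterior Hox list. Among 11 tested genes of the anteroposterior and dorsoventral list, 3 were higher in distal libraries (3 adjusted over the list alone, with 2 others higher in proximal). Hand2, a factor of the posterior limb bud, averaged 185 ± 58.8 against 18.4 ± 3.38 CPM (log2 fold change 3.33, SE 0.27; edgeR adjusted p = 7.62e-05). The list also held the forelimb factor Tbx5, higher by 1.82 (SE 0.17), and Tbx4, higher by 2.02 (SE 0.41). Its calls are therefore not all of genes of these axes. The Tbx4 call was lost without proximal library 2 or 3 or distal library 1 or 3 (adjusted p = 0.050 to 0.10). That list did not pass with camera (adjusted p = 0.33) and passed with fry (adjusted p = 0.036; 0.036 to 0.91 over all alternatives). Its median of -0.14 and mean of 0.36 differ in sign.

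Both reporter genes of the sort were higher in distal libraries. Sox9 (chromosome 11, 112782224 to 112787760) averaged 333 ± 55.2 CPM in distal and 104 ± 18.5 CPM in proximal libraries, a 3.20-fold difference (log2 1.68, SE 0.18; edgeR adjusted p = 0.0006). Scx (chromosome 15, 76457452 to 76459458) averaged 3022 ± 954 and 1364 ± 367 CPM, a 2.22-fold difference (log2 1.15, SE 0.25; edgeR adjusted p = 0.034). Its call was lost without distal library 1 (adjusted p = 0.096) and without proximal libraries 2 and 3 (0.10 and 0.094). The gate selected cells on both reporters in both regions.

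Of 14 tested chondrogenic genes, 9 passed, all higher in distal libraries (10 adjusted over the list alone), and 5 did not. The list, with a median of 1.55, passed with camera (adjusted p = 6.86e-13) but not with an estimated correlation (adjusted p = 0.13). They included the Sox9 partners Sox5 (2.38) and Sox6 (1.48), the ubiquitin ligase gene Wwp2 (1.45) and the matrix genes Col9a1 (1.62), Matn4 (1.88) and Col2a1, the major cartilage collagen, at 1038 ± 433 against 289 ± 118 CPM. Single left-out libraries ended the calls of Col9a1 (proximal 2 or distal 1), Sox6 (proximal 2 or 3, distal 1 or 2), Matn4 and Col2a1 (both proximal 1 or 2, distal 1), with adjusted p of 0.056 to 0.16, and the term for the library set ended that of Col2a1 (0.081). No prehypertrophic or hypertrophic gene of 3 tested passed, nor any when adjusted over the list alone (camera adjusted p = 0.95), with Mef2c at 0.92, Alpl at -1.03 and Pth1r at -0.30. Of 11 joint interzone genes, 5 were higher in distal and 1 in proximal libraries (7 and 1 adjusted over the list alone; camera adjusted p = 2.48e-06, 0.093 with an estimated correlation). Gdf5, the growth factor that marks forming joints, averaged 143 ± 32.1 against 22.2 ± 3.49 CPM (log2 fold change 2.70, SE 0.23; edgeR adjusted p = 8.67e-05). Erg, Nog, Gdf6 and Wnt4 were higher by 2.04, 1.99, 1.78 and 1.69, and Osr1 was lower in distal libraries, at 222 ± 14.5 against 442 ± 129 CPM. The calls of Erg, Nog, Gdf6, Wnt4 and Osr1 were each lost without proximal library 2 and without distal library 1, and some of them without proximal library 1 or 3 or distal library 2 (adjusted p = 0.053 to 0.18).

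Tendon genes did not move together. Of 20 tested, Scx and the proteoglycan gene Kera (2.35) were higher in distal libraries, while the fibrillar collagen genes Col5a2 (-1.32) and Col1a2 (-0.83) were higher in proximal ones; 3 and 8 passed adjusted over the list alone (camera adjusted p = 0.068). The calls were lost without 4 single libraries for Kera (all but proximal 1 and distal 3), 5 for Col1a2 (all but proximal 1) and 2 for Col5a2 (distal 1 or 2), with adjusted p of 0.060 to 0.11. Without proximal library 2 the tendon list passed towards proximal libraries (camera adjusted p = 0.0064; 0.0064 to 0.41 over all alternatives). Tnmd, a marker of later tendon cells, was at 16.1 ± 10.0 CPM in proximal and 4.22 ± 1.34 CPM in distal libraries and did not pass in edgeR (adjusted p = 0.0998). Tnmd passed with DESeq2 (adjusted p = 0.036), with adjusted p of 0.0036 to 0.28 over all alternatives. Of 8 osteoblast and perichondrium genes, Fgfr2 was higher in distal (1.03) and Postn in proximal libraries (-2.03), with 1 and 2 adjusted over the list alone (camera adjusted p = 0.47). The Fgfr2 call was lost without each library but proximal 1 (adjusted p = 0.081 to 0.19), and the Postn call without each distal library (0.11 to 0.13). Of 9 muscle connective tissue genes, Tbx4 and Tbx5 were higher in distal and Osr1 in proximal libraries, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.12; fry adjusted p = 0.0056; 0.0056 to 0.40 over all alternatives).

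**Figure D2:**
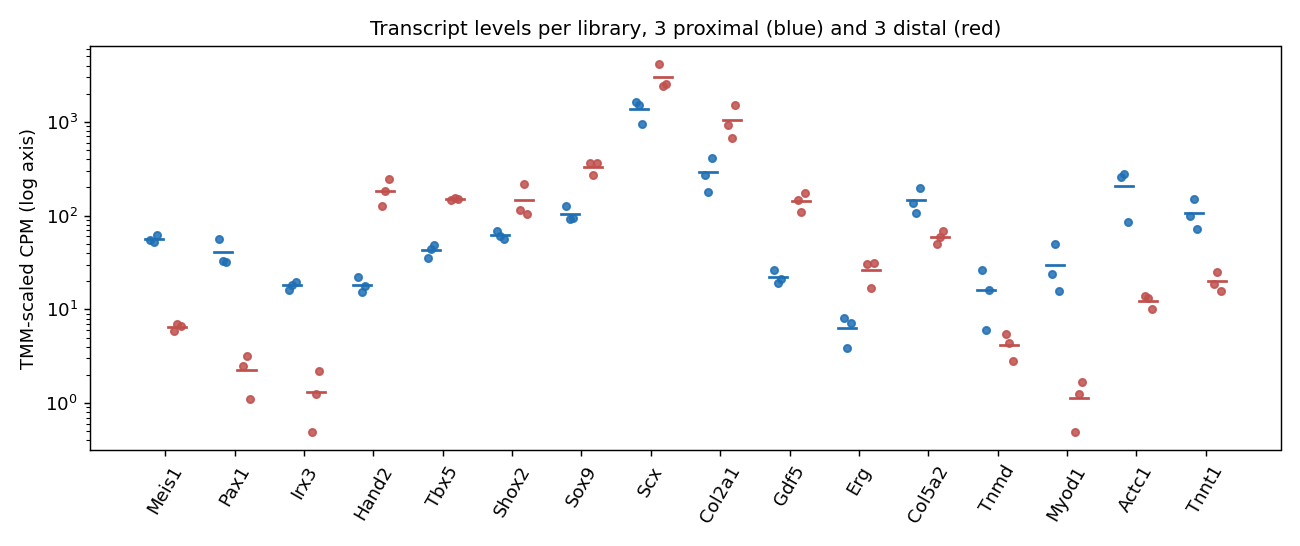
TMM-scaled CPM (log y axis) of 16 genes (x axis) in each of 3 proximal (blue) and 3 distal (red) libraries; points are libraries and lines are means. The regions do not overlap for the genes shown, including Tnmd, which did not pass the test; Meis1 averaged 56.6 and 6.53 CPM, Sox9 104 and 333 CPM, and Actc1 208 and 12.4 CPM in proximal and distal libraries.

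In the BMP list, Gdf5, Gdf6 and Nog were the 3 of 25 members that passed, all higher in distal libraries (6 adjusted over the list alone; camera adjusted p = 0.00011, 0.20 with an estimated correlation and 0.052 with fry). All 3 are also in the joint interzone list, so the 2 lists are not separate results. In the WNT list of 24, 4 were higher in distal and 3 in proximal libraries (7 and 4 adjusted over the list alone; camera adjusted p = 0.46): Frzb, a secreted WNT antagonist, averaged 45.9 CPM in distal and 9.88 CPM in proximal libraries (SE of the log2 fold change 0.39), and Wnt2, Rspo1 and Sfrp1 had log2 fold changes of -3.42, -3.88 and -1.13. The Frzb call was lost without proximal library 2 (adjusted p = 0.053) and the Sfrp1 call without proximal library 2 or 3 or distal library 2 (0.054, 0.078 and 0.070). Retinoic acid genes also split, with 2 of 16 higher in each region (3 and 3 adjusted over the list alone; camera adjusted p = 0.31). The retinoic acid-degrading enzymes went in opposite directions: Cyp26a1 was at 23.1 ± 12.7 CPM in proximal and 0.681 ± 0.750 CPM in distal libraries (log2 fold change -4.89, SE 0.67), and Cyp26b1 at 11.5 ± 5.27 and 50.2 ± 18.6 CPM. The retinoic acid receptor gene Rarg was higher in distal libraries by 1.30.

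In the FGF list of 14, Fgfr2 (1.03) and Fgfrl1 (0.77) were higher in distal and Fgf18 (-0.90) and Spry4 (-0.84) higher in proximal libraries, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.55). The call of Fgfrl1 was lost in all 6 fits with a library left out, and those of Fgfr2, Fgf18 and Spry4 in all but the one without proximal library 1 (adjusted p = 0.053 to 0.22 over the 4 genes). Of 23 ephrin and semaphorin genes, Plxna2 (-2.31) and Ephb1 (-1.65) were higher in proximal libraries (4 adjusted over the list alone, with 1 higher in distal). The list did not pass with camera (adjusted p = 0.085) and passed with fry (0.017) and with the stricter filter (0.039), with 0.017 to 0.30 over all alternatives. The Ephb1 call was lost without proximal library 2 or 3 or distal library 1 or 3 (adjusted p = 0.22, 0.17, 0.18 and 0.087). No member passed among 9 hedgehog genes (0 adjusted over the list alone; camera adjusted p = 0.029, 0.39 with an estimated correlation), where Hhip had 1.00 and Gli2 1.03. The hedgehog list call was lost without proximal library 1, distal library 1 or distal library 3 (adjusted p = 0.17, 0.19 and 0.13), with no filter (0.084) and with fry (0.19). No member passed among 16 TGF-beta genes (4 higher in distal and 1 in proximal adjusted over the list alone; camera adjusted p = 0.068), where Smad7 had 1.00. The TGF-beta list passed without proximal library 3 (adjusted p = 0.011; 0.011 to 0.41 over all alternatives).

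Transcripts of skeletal muscle were higher in proximal libraries. Of 8 tested muscle genes, 7 passed, all in that direction (8 adjusted over the list alone; camera adjusted p = 8.12e-14, 0.093 with an estimated correlation). The myogenic factor Myod1 (chromosome 7, 46376474 to 46379099) was at 24.1, 50.2 and 15.8 CPM in proximal and 0.495, 1.26 and 1.67 CPM in distal libraries 1 to 3 (log2 fold change -4.66, SE 0.62; edgeR adjusted p = 0.0024). Myog, the cardiac actin gene Actc1 and the troponin gene Tnnt1 had log2 fold changes of -3.58, -4.05 and -2.43, and Msc, which is expressed in muscle precursors among other cells, -4.22. The Actc1 call was lost with proximal library 1 and distal library 3 left out together (adjusted p = 0.077). These muscle transcripts differed between the regions, as did the Hox, proximal and distal limb regulator and chondrogenic lists, some in the other direction. The comparison of regions alone does not separate these groups. Of 3 tested endothelial genes, Ramp2 was higher in proximal libraries at -1.18 (2 of 3 adjusted over the list alone; camera adjusted p = 0.0025, 0.22 with an estimated correlation). The Ramp2 call was lost without each library but distal 3 (adjusted p = 0.064 to 0.21).

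Other proximal genes with large changes were the neuropeptide genes Npy, at 162 ± 48.3 against 2.99 ± 0.458 CPM (log2 fold change -5.74, SE 0.32), and Crh (-4.83), the alcohol dehydrogenase gene Adh1 (-5.24) and the antisense gene Hoxb5os (-4.88), whose span covers Hoxb5 and Hoxb6 on the other strand. The annotated 3' ends of Hoxb5 (96306121) and Hoxb6 (96301569) lie inside the span of Hoxb5os. As the strand setting of the counting is not given, reads there cannot be told apart. In distal libraries Fam101a was higher by 2.83.

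The lists of blood, immune, nerve and skin markers had fewer than 3 tested members each and were not tested as lists. Of the erythroid genes, Hbb-y had 159 counts and Hba-x 61 counts in proximal library 3 and at most 19 and 7 counts in any other library. Myeloid genes had at most 11 counts in any library. In the Schwann cell and neuron list Sox10 had 2 to 18 counts and the neuronal gene Stmn2 was higher in distal libraries by 1.70 (SE 0.32; edgeR adjusted p = 0.016). Stmn2 was not among the genes named by rule or afterwards, and its call was not followed in the alternatives. The neuronal cytoskeleton and growth cone genes Nefl and Gap43, outside that list, went the other way (-4.27 and -1.68). In the epidermal list Krt14 had at most 3 counts while Krt10 had 20 to 43 counts in every library.

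Of 31 proliferation genes none passed, and none when adjusted over the list alone, with Mcm2 at 0.60 and Top2a at 0.49; the list as a whole passed towards distal libraries with a median of 0.16 (camera adjusted p = 0.010, 0.26 with an estimated correlation, 0.16 without proximal library 2 and 0.16 with fry). Of 17 hypoxia and glycolysis genes none passed over all genes and 1 did adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.0010, 0.43 with an estimated correlation, 0.17 without distal library 1 and 0.32 with fry). No gene of the 19 tested for dissociation stress passed under either adjustment (camera adjusted p = 0.12). The stress list passed towards distal libraries without proximal library 1 or distal library 3 (adjusted p = 0.015 and 1.5e-06), and its direction turned without distal library 1 (0.72) and with the term for the library set (0.68). Of 12 imprinted growth genes, Dlk1 (-1.40), Peg10 (-1.34) and Plagl1 (-1.88) were higher in proximal libraries (7 adjusted over the list alone, with 1 higher in distal; camera adjusted p = 1.43e-05, 0.091 with an estimated correlation). The Plagl1 call was lost without proximal library 3 or distal library 1 or 2 (adjusted p = 0.068, 0.064 and 0.072). The 3 tested sex-linked genes did not pass under either adjustment (camera adjusted p = 0.54). In all, 14 of 26 lists passed with the preset correlation and 3 with an estimated one. Some of the lists that passed share members, so they are not all separate results.

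The libraries also differed in a way that crossed the regions. The pre-ribosomal RNA Rn45s took 11.7% of counts in proximal library 1, 4.63% in distal library 1 and 6.81% in distal library 2, and 2.94%, 2.20% and 2.98% in proximal libraries 2 and 3 and distal library 3. Dividing the libraries at a share of 4% leaves only 1 library of one region in each set, so no test was made within a set. With a term for the set, chosen after seeing the data, 535 genes passed in edgeR, among them 316 of the 322.

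**Figure D3:**
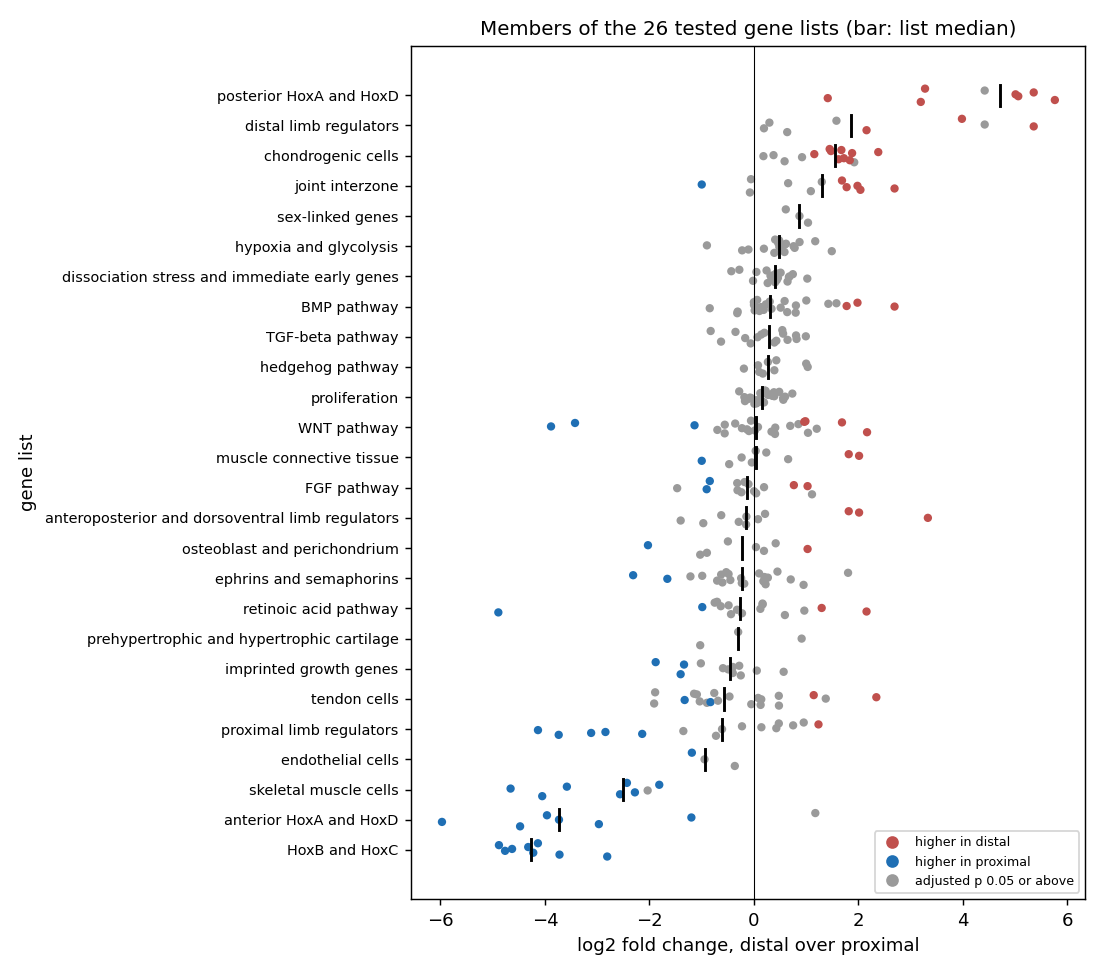
Log2 fold change (x axis, distal over proximal) of each tested member (point) of the 26 tested gene lists (y axis), with the list median as a black bar; colour marks genes past an adjusted p of 0.05. The posterior HoxA and HoxD list has a median of 4.72, the chondrogenic list 1.55, the skeletal muscle list -2.49 and the HoxB and HoxC list -4.27.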

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

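The settings with Rn45s left out, with a term for the library set, and with the extremes of the second component left out were chosen after seeing the data. Counts of changed genes were 322 in total, 106 higher in distal and 216 higher in proximal libraries. Leaving out each library in turn gave 171 to 334, 42 to 114 and 114 to 220. With 2 libraries in 1 region, the spread rests on 3 degrees of freedom. None of the 322 genes changed sign under any alternative fit; 163 (without distal replicate 1) to 271 (without proximal replicate 1) of them were still called with a library left out. The 20 genes with the largest changes were picked from these same libraries as called and non-overlapping. That they were called in all 6 of these fits is therefore partly built into the choice. Of the 70 called genes named by rule, 46 were called in all 6. The 24 lost in at least 1 were Scx, Shox2, Hoxa9, Cyp26b1, Tbx4, Erg, Nog, Gdf6, Wnt4, Osr1, Kera, Col5a2, Col1a2, Col9a1, Fgfr2, Fgfrl1, Fgf18, Spry4, Postn, Frzb, Sfrp1, Ephb1, Ramp2 and Plagl1. Of the 31 genes named after their values were seen, 8 were lost in at least 1 alternative (Hoxa7, Col2a1, Matn4, Sox6, Col6a1, Fbn1, Igfbp5 and Foxc2). An adjusted p of 0.01 left 143 genes, 42 higher in distal and 101 higher in proximal libraries, by construction. The term for the Rn45s library set gave 535 genes, with 214 higher in distal; leaving out proximal library 1 and distal library 3 together gave 862, 441 and 421. The cause of these 2 increases was not tested. The other scalings, filters and tests gave 277 to 383 genes, within 1.5 times the main count, and no scaling moved the median of all genes by more than 0.01 on the log2 scale.

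The replicate number as a block gave 465 genes, 184 of them higher in distal libraries, and 321 of the 322 calls were kept. After region means were subtracted, same-numbered libraries correlated at 0.354, -0.14 and 0.48. Of the differently numbered pairs, proximal library 1 with distal library 2 correlated at 0.359. Proximal library 2 with distal library 3 correlated at 0.29, and the rest were negative. These values are interdependent and leave pairing open.

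Fixed lists past the threshold numbered 14, and 12 to 15 with a library left out. The replicate block gave 16, keeping all 14 and adding 2. Leaving out the second-component extremes ended 1 call and added 1. An estimated correlation left 3 and fry 13. Fry ended the calls of the BMP, hedgehog, proliferation and hypoxia lists and called the anteroposterior and dorsoventral, ephrin and muscle connective tissue lists. The hedgehog call also ended with no filter and with the second-component extremes left out (0.43). The estimated correlation changes the degrees of freedom of the test as well, and the effects of these were not separated. No list that passed changed direction under any alternative. Lists that did not pass and changed direction were the anteroposterior and dorsoventral list with the second-component extremes left out (adjusted p = 0.85), the WNT list with no filter (0.53), the FGF list with the stricter filter (0.95), the stress list with the library set term (0.68) and without distal replicate 1 (0.72), the osteoblast list without proximal replicate 3 (0.94; 0.26 to 0.94 with a library left out), and the hypertrophic list with the library set term (0.88), the extremes left out (0.51) and a library left out (0.31 to 0.90). The stress list ranged from 1.5e-06 to 0.72 with a library left out and passed with proximal replicate 1 or distal replicate 3 left out (adjusted p = 0.015 and 1.5e-06). Of the 70 called genes named by rule, 9 were lost in at least 1 other alternative (Actc1, Ephb1, Fgf18, Fgfrl1, Nog, Postn, Ramp2, Shox2 and Spry4). Of 50 uncalled ones, 25 were called in at least 1 alternative and 3 changed sign: Xist with the library set term (-0.37), limma-voom (-0.18) and without distal replicate 1 (-3.55 to 1.71 with a library left out), Ddx3y without distal replicate 2 (-0.26 to 3.25), and Dlx5 with the extremes left out (-0.052) and a library left out (-0.21 to 1.46). At this depth, by the simulation, a log2 change of 1 was called in 45% of genes, so absent calls among small changes are weak evidence.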

Other observations

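The tests of GC content, transcript length and other splits of the libraries were written before their results were seen; the tests of replicate number, sex and muscle cells were chosen only after the result was seen. Genes in the next paragraph were picked from the table after seeing their values, so their grouping is not tested.

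Several contractile and cytoskeletal genes were higher in proximal libraries: Acta2, smooth muscle actin, had a log2 fold change of -3.20 (SE 0.40), Pgm5 -3.03, Flnc -1.92, Tpm2 -1.42 and Tpm1 -0.89. Genes of the insulin-like growth factor system were also higher there, with Igf1 at 334 ± 94.7 against 114 ± 15.0 CPM, Igfbp3 at -2.00 and Igfbp5 at -1.42. The matrix genes Col6a1, Col6a2 and Fbn1 had -0.88, -1.54 and -1.05, the neuronal cytoskeleton and growth cone genes Nefl and Gap43 -4.27 and -1.68, and Zic1 -3.12. On the distal side stood transcription factor genes, with Foxc1 at 207 ± 26.2 against 41.7 ± 7.82 CPM, Foxd2 higher by 2.41, Foxc2 by 1.63, Gsc by 1.82, and the patterning genes Mab21l2 by 2.09 and Mab21l1 by 1.53. Single left-out libraries ended the calls of Igfbp5 (proximal 2, distal 1 or 2), Col6a1 and Fbn1 (both proximal 3, distal 1 or 2) and Foxc2 (proximal 2 or distal 2), with adjusted p of 0.053 to 0.15.

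Across the 8 tested HoxA genes the Spearman correlation between gene start and log2 fold change was 0.881. The order was noticed in these same values, so the correlation describes them and tests nothing. Genes of one cluster are not independent replicates, and the annotated spans of several overlap.

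The libraries with a higher Rn45s share (proximal 1, distal 1 and distal 2) differed from the other 3 in more genes than the regions did: of the 10 splits of the 6 libraries into 3 and 3, this one gave 488 genes in edgeR, the regions 322 and each of the other 8 gave 0 (78 to 359 at an unadjusted p under 0.05). This points to a structure of the libraries, and with a term for it the regions differed in 535 genes; 2 of 10 splits reached the real count, 1 of 10 for the lists (14 against 11 in the highest other), and 10 splits are too few for a share under 0.05. GC content is a candidate explanation for the structure: across 9177 genes (96.5% with a value), the Spearman correlation between the difference of the sets, adjusted for region, and the GC content of the last 500 bases was -0.365, against -0.105 for the regional fold change. The correlation with transcript length was -0.229, between the bounds set beforehand, so length stays open. GC and length together accounted for 24.99% of the variance of the set difference and 0.63% of that of the regional fold change. The set difference was fitted on the log2 of CPM plus 1, and the regional value was edgeR's fold change. The correlations and shares of the 2 are therefore not on a like scale. Sex alone is argued against, since both of the 2 sets held libraries with mainly Xist and with mainly Y-linked transcripts. Replicate number alone does not account for the sets, since number 2 had a library in each. Numbers 1 and 3 each fell within a single set, so a part of replicate number stays open. No other biological explanation was tested.

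The muscle transcripts of the proximal libraries may come from muscle cells among the sorted cells. All 8 tested muscle genes were higher in proximal library 2 than in 3. The median difference was 1.53 on the log2 scale (interquartile range 1.02 to 1.68), as a varying share of such cells would give. Their most abundant member Actc1 averaged 208 ± 105 CPM in proximal libraries. Proximal library 1 was not in this comparison, and its ratio to library 2 differed between genes. Actc1 stood at 262 and 275 CPM in proximal libraries 1 and 2, and Myod1 at 24.1 and 50.2 CPM. The gate required both reporters, so expression in the sorted progenitors themselves stays open and was not tested. Within this pair of libraries, the same cells are argued against as the source of the HoxB and HoxC transcripts. Those 8 genes differed by a median of -0.20 (interquartile range -0.41 to 0.06), with 2 of them higher in library 2. The test was chosen after the result was seen and holds a single library on each side, so this is weak evidence.

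Libraries with the same number did not always hold transcripts of the same sex. Number 1 had 27 and 65 Xist counts and number 2 had 28 and 43 Ddx3y counts with 0 Xist counts, in proximal and distal libraries. In number 3, the proximal library had 17 Xist, 2 Ddx3y and 1 Kdm5d counts and the distal library 2, 16 and 13. Fisher's exact test of Xist against the sum of Ddx3y and Kdm5d in number 3 gave a two-sided p of 1.1e-08, which covers counting error only and takes each count as a separate molecule, although the use of molecular identifiers is not given. As far as that holds, it argues against both libraries coming from the same embryos; a shared litter, or a mislabelled number, stays open as an untested explanation.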
